A study of Homo sapiens with 6 samples.

How the data were processed

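Total RNA of MDA-MB-231 cells was extracted with Trizol and hybridised as biotin-labelled cRNA to 6 Illumina BeadChip arrays, 2 per group, per the labels. All 6 arrays carry the name of the same chip in the labels, so chip and group are not confounded and no batch was available to block on. The letters in the array names run with the group: A and B control, C and D DICER1-sh, E and F DROSHA-sh. An effect of position or order on the chip could therefore not be separated from group. The first deposited table holds the mean bead intensity of each probe on each array, on a linear scale with no scaling between arrays, per the file headers and the values. It also holds a detection p-value per probe and array, per the file headers, which runs in steps of 1 over 770 as a comparison with that many negative control probes would give. The second table that the authors deposited holds processed intensity values of the same arrays. Its values reach down to -58.6 on every array and have nearly the same quartiles on all arrays, with medians of 21.9 to 22.0, so they were background-subtracted and brought to a common distribution on a linear scale. Each array's values kept the rank order of the first table. The submitters' processing notes name GenomeStudio, with a version not given in the sources used here, and the method of normalization was not given either.

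Samples were grouped by the cell label (control, DICER1-sh or DROSHA-sh) and carry the replicate numbers of the labels. Raw median intensity was between 150.2 and 166.7 per array. Between 42.0% and 44.4% of probes had a detection p-value below 0.05, which sets how many genes could be measured. For arrays, their number limits the precision, and with 2 arrays per group the fit kept 3 residual degrees of freedom and borrowed 4.34 more from all genes.

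Intensities were background-corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, with normexp fitted through the detection p-values, an offset of 16, quantile normalization and log2. Probes were kept where the detection p-value was below 0.05 on at least 2 of 6 arrays, which left 22091 of 47319. Platform annotation gave 30112 probes 1 gene symbol, 8 several and 17199 none. Symbols were brought up to date for 30073 probes through their Entrez numbers in the RefSeq gene table of assembly GRCh38.p14, whose coordinates were not printed because the probes name no build. No gene was named from a probe with several symbols. Where a gene had several kept probes, as 3345 did, the probe with the highest mean over all 6 arrays stood for it. Probes without a symbol were tested as themselves, which gave 17790 tested features, of which 12083 were named genes and 32.1% unnamed. Probe levels were set against the same probe only.

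All 3 groups were fitted together with lmFit and eBayes, so that they shared 1 estimate of the spread, and the 3 comparisons between groups were read from that fit with Benjamini-Hochberg adjusted p-values and a threshold of 0.05. Every adjusted p given for a gene comes from limma. Gene lists were tested with limma's camera at its preset correlation of 0.01 between members, adjusted over 29 lists and the miRNA gene probes within a comparison. An estimated correlation and fry, which tests whether a list's genes move one way on balance, were alternatives, and both called 0 lists in each comparison. The lists covered miRNA machinery and host transcripts, published targets of 7 miRNA families, pathways, mesenchymal and epithelial markers, markers of other cell types (luminal breast, melanocytic, leukocyte, fibroblast and HEK293) and genes that respond to RNA quality and handling. The miRNA gene probes are those whose symbol is a miRNA gene. The array carries 560 of them, and 65 genes were tested. Such a probe lies within or beside a hairpin and cannot tell a primary transcript from a host transcript.

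A gene that was not above background on any array of a group has only a bound there. It is given as "at least N-fold", the mean log2 value of the brighter group against the dimmer group's mean of, per array, the higher of the lowest value among detected probes and the probe's own value. Such a bound holds for this background correction alone. The genes named were chosen by a rule: DICER1 and DROSHA, up to 10 highest and 10 lowest changes past the threshold, up to 4 members past the threshold per list, and otherwise the member of each list with the smallest p. Genes named outside that rule are said to be chosen after their values were seen, except the members of counts that are listed in full. The groups, the tests, the lists, the rule and most alternatives were fixed before the data were examined.

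The overlap of the 2 knockdowns was set against 100 simulated draws of unchanged groups with shared control arrays, once with independent noise and once with noise that followed the axis along which the arrays of a group differed. That axis is the first component of the arrays' deviations from their group means. Fitted as a covariate it takes up part of those same deviations, so the spread falls by construction. In DROSHA-sh against control the median standard error fell from 0.328 to 0.220. Calls gained with the covariate are therefore no independent support. The replicate numbers were checked as pairs: deviations of control 1 and DICER1-sh 1 correlated at r = -0.63 across genes, and those of DROSHA-sh 1 at -0.03 with control 1 and 0.02 with DICER1-sh 1, so the numbers did not pair the samples.

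The method was tested on simulated data with the real genes' means and spread, 20 draws and 200 changed genes in each. With independent noise it recovered 81.6% of 4-fold and 99.2% of 8-fold changes for DICER1-sh, 81.2% and 98.2% for DROSHA-sh, but 4.1% and 4.3% of 2-fold changes, with a median of 8 and 7.5 unchanged genes called per draw. With structured noise it recovered 37.0% of 4-fold and 67.0% of 8-fold changes for DICER1-sh, and 26.7% and 48.1% for DROSHA-sh. There the median of false calls was 0 for both, but 1 of the 20 draws called 14340 unchanged genes for DICER1-sh. A list shifted by a log2 of 0.5 was called by the preset camera in 19 to 20 of 20 draws, and unshifted lists were called in 6.74% (DICER1-sh) and 5.43% (DROSHA-sh) of cases with that noise. The test with an estimated correlation called the shifted list in 0 of 20 draws with independent noise and in 3 and 4 of 20 with structured noise.

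Alternatives changed the background correction, the normalization, the source of the values, the probe filter, the probes per gene, the spread, the arrays in the fit, the replicate block, the threshold and the test of the lists, and left out each array in turn. A test of miRNA seed matches in 3' untranslated regions was planned and not run, because no sequences were used here. Figures were drawn with matplotlib 3.10.9.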

Results

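Gene expression was measured in MDA-MB-231, a basal-like human breast cancer cell line, with and without stable expression of a small hairpin RNA against DICER1 or DROSHA. DROSHA is the nuclear enzyme that cuts the hairpin of a miRNA out of its primary transcript. DICER1 is the cytoplasmic enzyme that cuts that hairpin into the mature miRNA. Each of the 3 groups, called control, DICER1-sh and DROSHA-sh here, had 2 Illumina expression arrays hybridised with biotin-labelled cRNA from total RNA. The labels do not say whether the control cells carried a hairpin of their own. They also do not say whether the 2 arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. Between 19877 and 21026 of the 47319 probes were above background on an array, 42.0% to 44.4% of them, and the number of arrays limits the precision. The design asks which mRNAs respond when the synthesis of miRNAs is inhibited.

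The transcript targeted by each hairpin was at its lowest level in the cells that expressed that hairpin. In DICER1-sh cells the brightest DICER1 probe (ILMN_1772692) had a log2 intensity of 8.54 ± 0.17 against 9.95 ± 0.84 in control cells (SD, n = 2), 2.67-fold lower. In DROSHA-sh cells the brightest DROSHA probe (ILMN_1790410) had a log2 intensity of 8.99 ± 0.02 against 11.25 ± 0.47 in control cells (SD, n = 2), 4.77-fold lower. The second measured probe of each gene was 3.29-fold lower for DICER1 (ILMN_2349831) and 4.15-fold lower for DROSHA (ILMN_2152095). On the DROSHA-sh arrays ILMN_2152095 stood at 5.749 and 5.755, near the lowest detected values of 5.745 and 5.734. Its fold therefore depends on the background correction. DICER1 in DROSHA-sh cells stood at a log2 change of 0.36 with a standard error of 0.41, and DROSHA in DICER1-sh cells at -0.14 with a standard error of 0.34, or 0.20 without control 1. The second probes stood at 0.10 for DICER1 in DROSHA-sh cells and -0.61 for DROSHA in DICER1-sh cells. Both arrays of the targeted group lay below all 4 other arrays for each of these 4 probes. In limma over all genes, neither target passed an adjusted p of 0.05 (DICER1 0.969, DROSHA 0.479). The DICER1 estimate of -1.42 moved to -0.82 without control 1 and to -2.01 without control 2.

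**Figure D1:**
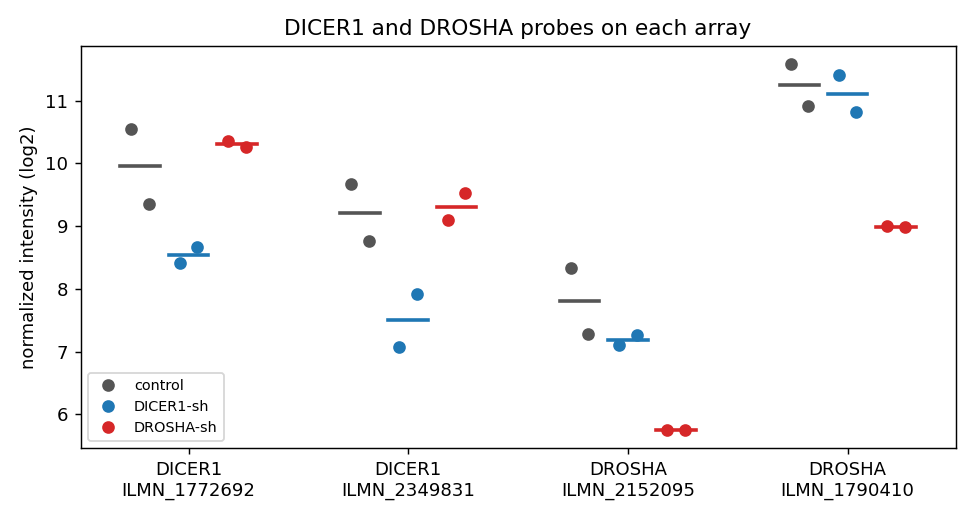
Normalized log2 intensity (vertical axis) of the 4 measured probes of DICER1 and DROSHA (horizontal axis) on each of the 6 arrays, with points for single arrays and bars for the means of 2 arrays. For ILMN_1772692 the DICER1-sh mean was 8.54 against 9.95 in control, and for ILMN_1790410 the DROSHA-sh mean was 8.99 against 11.25.

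The comparison of DICER1-sh with control cells asks which mRNAs respond to less DICER1. MMP1, the interstitial collagenase, had a log2 change of -1.20 with a standard error of 0.29, from 12.37 ± 0.29 in control to 11.17 ± 0.27 in DICER1-sh (SD, n = 2). CLDN1, a tight junction protein, stood at -1.20 with a standard error of 0.40, and IFIT2, an interferon-induced gene, at -0.64 with a standard error of 0.31. On the higher side stood CCND2, a D-type cyclin, at 0.85 with a standard error of 0.29, and HLA-DRA, an antigen-presenting molecule, at 0.66 with a standard error of 0.27. None of these genes passed the test. Of 17790 genes and unnamed probes, limma placed 0 below an adjusted p of 0.05, the smallest adjusted p being 0.969, and 343 below an unadjusted p of 0.05 (190 of them higher), where chance gives 889.5. A total of 54 were at least 2-fold higher and 112 at least 2-fold lower. The 2 groups did not overlap for 20.3% of genes, where chance gives 33.3%.

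Among the gene lists, 1 passed in DICER1-sh cells. Nuclear-encoded subunits of the respiratory chain (oxidative phosphorylation) stood at a mean log2 change of 0.28, with 32 of 35 members above 0 and COX5A, a subunit of cytochrome c oxidase, at 0.47 (adjusted p = 0.00753 in limma's camera). The call was lost at an adjusted p = 0.921 with an estimated correlation, and the mean was -0.12 without control 1 and 0.68 without control 2. The same genes differed by -0.80 between control 1 and control 2 and by -0.28 between DICER1-sh 2 and DICER1-sh 1, more than the mean difference between the groups in the control pair. Ribosomal proteins stood at 0.15 (adjusted p = 0.218) and differed by -0.39 within the control pair. Replication-dependent histones stood at 0.27 and luminal breast cell markers at 0.36 (adjusted p = 0.0653 for both), with differences of -0.69 and -0.53 within the control pair. GATA3, a luminal transcription factor, was not above background on either control array and was at least 1.40-fold higher in DICER1-sh. No gene of any list passed when adjusted over the list alone.

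The 7 lists of published miRNA targets had mean log2 changes between -0.10 (miR-30) and 0.10 (let-7) in DICER1-sh cells, with no adjusted p in camera below 0.555. DICER1, the hairpin's own target, is a member of the let-7 list and of the list with miR-221 targets. It stood at -1.42, which lowers the means of both lists. The let-7 median was 0.12, with 12 of 18 members above 0. The list with miR-221 targets had a mean of -0.04 and a median of -0.03. Neither list was tested without DICER1. FN1, the fibronectin gene and a listed target of the miR-200 family, was at least 1.25-fold higher. COL5A1, a fibrillar collagen and listed miR-29 target, stood at 0.44 with a standard error of 0.26. TRIAP1, a p53 target, stood at 0.52, VEGFA at -0.43 and MSMO1, an enzyme of cholesterol synthesis, at -0.55. The lists of the miRNA machinery (-0.18), miRNA host transcripts (0.03), interferon response (0.15), NF-kB targets (0.03), cell cycle (-0.06), p53 targets (0.11), stress response (0.13), hypoxia and glycolysis (-0.04), cholesterol synthesis (0.02), extracellular matrix (0.04), TGF-beta and YAP targets (-0.16), mesenchymal markers (0.01), epithelial markers (-0.02) and immediate early genes (0.03) did not pass the test either. The median had the other sign than the mean for miR-29 targets (-0.03), mesenchymal markers (-0.09) and epithelial markers (0.23), and camera gave a downward direction for mesenchymal markers and cholesterol synthesis. Markers of melanocytic cells stood at -0.14, of leukocytes at 0.18, of fibroblasts at -0.19 and of the HEK293 line at 0.25, and none of them passed.

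The comparison of DROSHA-sh with control cells asks which mRNAs respond to less DROSHA. Several of the larger differences were in probes named for miRNA genes. MIR21, the gene of an abundant miRNA of cancer cells, had a log2 intensity of 8.54 ± 0.19 in DROSHA-sh cells (SD, n = 2) and was not above background on the control or DICER1-sh arrays. Its signal was at least 7.20-fold higher than in control (measured log2 difference 3.52, standard error 0.28, adjusted p = 0.0552 in limma). The size depends on the background correction: the measured log2 difference of MIR21 was 1.87 with none and 2.27 with normexp at an offset of 50, both under that bound. MIRLET7A1 was at least 3.89-fold, MIR181B1 at least 2.78-fold and MIR24-1 at least 2.26-fold higher than in control. MIR221, above background on all 6 arrays, stood at 1.78 with a standard error of 0.33, and MIR185 at 1.40 with a standard error of 0.27.

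Of 65 miRNA genes tested, 10 were at least 2-fold higher in DROSHA-sh cells by their measured means and 0 at least 2-fold lower, where 0.919 higher are expected among genes of like control level. Taking the bound where control was not above background, 7 of them reached 2-fold, the 6 genes named above and MIRLET7D at 1.46. The other 3 were MIRLET7I at least 1.32-fold, MIR29B1 at least 1.19-fold and MIR181A1 at least 1.41-fold higher, and the last 2 were above background on 1 of the DROSHA-sh arrays. In total, 7 of the 10 were not above background on either control array. As a group the 65 miRNA genes that passed the probe filter stood at a mean log2 change of 0.38 (adjusted p = 2.59e-05 in camera), with 42 of 65 above 0. Their median was lower, at 0.20. The call was lost at an adjusted p = 0.273 with an estimated correlation, and without the probe filter, where the mean was 0.055 (adjusted p = 0.603). The filter can admit a probe through its change: 7 of the 65 were above background on both DROSHA-sh arrays and no other, against 1 for DICER1-sh. Among the 19 miRNA genes above background on all 6 arrays the mean was 0.35 in DROSHA-sh (adjusted p = 0.0296 in camera), a test chosen after the results were seen. Adjusted over the list alone, 8 passed and were higher: MIR21, MIRLET7A1, MIR181B1, MIR24-1, MIR221, MIRLET7D, MIR185 and MIRLET7I. In DICER1-sh cells the same probes had a mean log2 change of 0.03 (adjusted p = 0.946), with 1 gene, MIR373, at least 2-fold higher by its measured means and 1 at least 2-fold lower. MIR373 was not above background in control cells and was at least 1.43-fold higher in DICER1-sh.

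**Figure D2:**
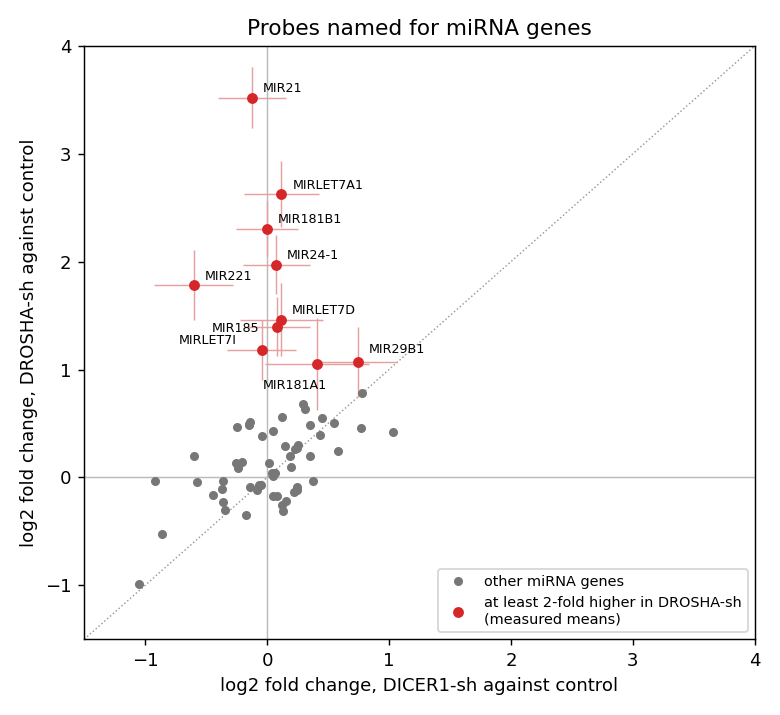
Log2 fold change of 65 miRNA genes in DROSHA-sh against control (vertical axis) and in DICER1-sh against control (horizontal axis), with 1 standard error as bars on the 10 genes that were at least 2-fold higher in DROSHA-sh by their measured means. Values of genes not above background are measured means, not bounds. MIR21 stood at 3.52 in DROSHA-sh and -0.12 in DICER1-sh, and the dotted line marks equal changes.

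Genes of the NF-kB response were higher as a group than other genes in DROSHA-sh cells in camera with its preset correlation. Their mean log2 change was 0.48, with 26 of 29 members above 0 (adjusted p = 2.59e-06). The call was lost at an adjusted p = 0.273 with an estimated correlation, and no member passed over all genes or adjusted over the list alone. CCL20, a chemokine, stood at 1.12 with a standard error of 0.29, and IL6, an inflammatory cytokine, at 1.21 with a standard error of 0.35. The list differed by -0.18 between control 1 and control 2 and by 0.05 within the DROSHA-sh pair.

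Replication-dependent histones, whose mRNAs normally end without a poly(A) tail, stood at a mean log2 change of 0.84 in DROSHA-sh cells, with 11 of 13 above 0 (adjusted p = 2.31e-07 in camera). The call was lost at an adjusted p = 0.522 with an estimated correlation, and the mean was 0.50 without control 1 and 1.19 without control 2. H2BC5 went from 9.22 ± 0.59 in control to 10.77 ± 0.25 in DROSHA-sh (SD, n = 2), a log2 change of 1.56. Adjusted over the list alone, 4 passed and were higher: H1-2, H2BC5, H2BC12 and H4C8. Its members differed by -0.69 between control 1 and control 2. Cell cycle genes stood at a mean log2 change of -0.27, with 14 of 58 above 0 (adjusted p = 2.28e-05 in camera). That call was also lost at an adjusted p = 0.522 with an estimated correlation, and the mean was -0.15 without control 1 and -0.39 without control 2. CDC25A, a phosphatase that drives entry into S phase, went the other way at 0.90 with a standard error of 0.34. The list differed by 0.24 between control 1 and control 2. Oxidative phosphorylation genes stood at a mean log2 change of 0.31 (adjusted p = 0.00557 in camera), with NDUFS4, a complex I subunit, at 0.58. That call was lost at an adjusted p = 0.951 with an estimated correlation, and the mean was -0.090 without control 1. With the arrays' score on their main within-group axis as a covariate the mean was 0.06 (adjusted p = 0.536 in camera).

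The 7 lists of published miRNA targets did not pass in DROSHA-sh cells without a covariate. The let-7 targets had a mean log2 change of 0.25 with 13 of 18 above 0 (adjusted p = 0.196). They passed with the axis as a covariate, at a mean of 0.24 (adjusted p = 0.0220 in camera), and no longer when the correlation was estimated as well. The mean was -0.03 for the miR-21 targets, 0.02 for the miR-17 family, -0.14 for miR-29, -0.13 for miR-30, -0.06 for miR-221 and miR-222 and -0.06 for the miR-200 targets. Among their members, CDKN1A, a cyclin-dependent kinase inhibitor on the miR-17 family and p53 lists, stood at 1.00 with a standard error of 0.30. CYP1B1, a cytochrome P450 on the miR-200 list, stood at 1.09, ADAM19, a metalloprotease on the miR-30 list, at 1.44, and TNFSF10, the death ligand TRAIL on the miR-221 and miR-222 list, at 0.60. These genes did not pass the test.

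Of the other lists, the means were 0.21 for immediate early and heat shock genes (EGR1 at 1.19), 0.10 for the interferon response (IFI27 at 1.29), 0.14 for p53 targets, 0.07 for the stress response (CTH at -0.66), 0.05 for hypoxia and glycolysis (P4HA2 at 0.76) and -0.17 for cholesterol synthesis. INSIG1, which holds back the activation of cholesterol synthesis, stood at -1.47 with a standard error of 0.40, and its dimmer second probe at -0.75. The means were 0.09 for extracellular matrix and 0.05 for mesenchymal markers, with TGFBI at 0.92 on both lists, -0.01 for TGF-beta and YAP targets (SMAD6 at -0.99) and 0.19 for epithelial markers (CLDN3 at least 1.22-fold lower). Ribosomal proteins stood at 0.14, luminal breast cell markers at 0.23 (AGR2 at 0.96), melanocytic markers at -0.01, leukocyte markers at 0.09, fibroblast markers at -0.07 and HEK293 markers at 0.09. Without a covariate none of these lists had an adjusted p in camera below 0.102. With the axis as a covariate cholesterol synthesis passed at a mean of -0.23 (adjusted p = 0.00777), and no longer when the correlation was estimated as well. The miRNA machinery stood at -0.14 and miRNA host transcripts at 0.03. The median and the direction in camera were negative for the host transcripts (-0.04), the median lay just on the other side of 0 from the mean for the miR-17 family, extracellular matrix, mesenchymal and TGF-beta lists, and camera gave an upward direction for the TGF-beta list. Adjusted over the list alone, 1 gene passed in each, DROSHA itself and MIR100HG, the host of miR-100 and let-7a-2, which had a log2 change of 2.09 with a standard error of 0.29.

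Over all genes in DROSHA-sh against control, limma placed 0 of 17790 below an adjusted p of 0.05, the smallest being 0.0552 for MIR21, and 527 below an unadjusted p of 0.05 (294 higher), where chance gives 889.5. A total of 170 were at least 2-fold higher and 178 at least 2-fold lower, and the groups did not overlap for 37.4% of genes, where chance gives 33.3%. The count was 1, MIR21, with median scaling, cyclic loess or the deposited normalized values, and 3 with the arrays' score on their main within-group axis as a covariate. A replicate block that paired control 1 with DICER1-sh 2, chosen after the data were seen, gave 10. The deposited values were raised to a floor of 16 before log2. There MIR21 differed by the same 4.47 from control and from DICER1-sh, so the floor sets that size.

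**Figure D3:**
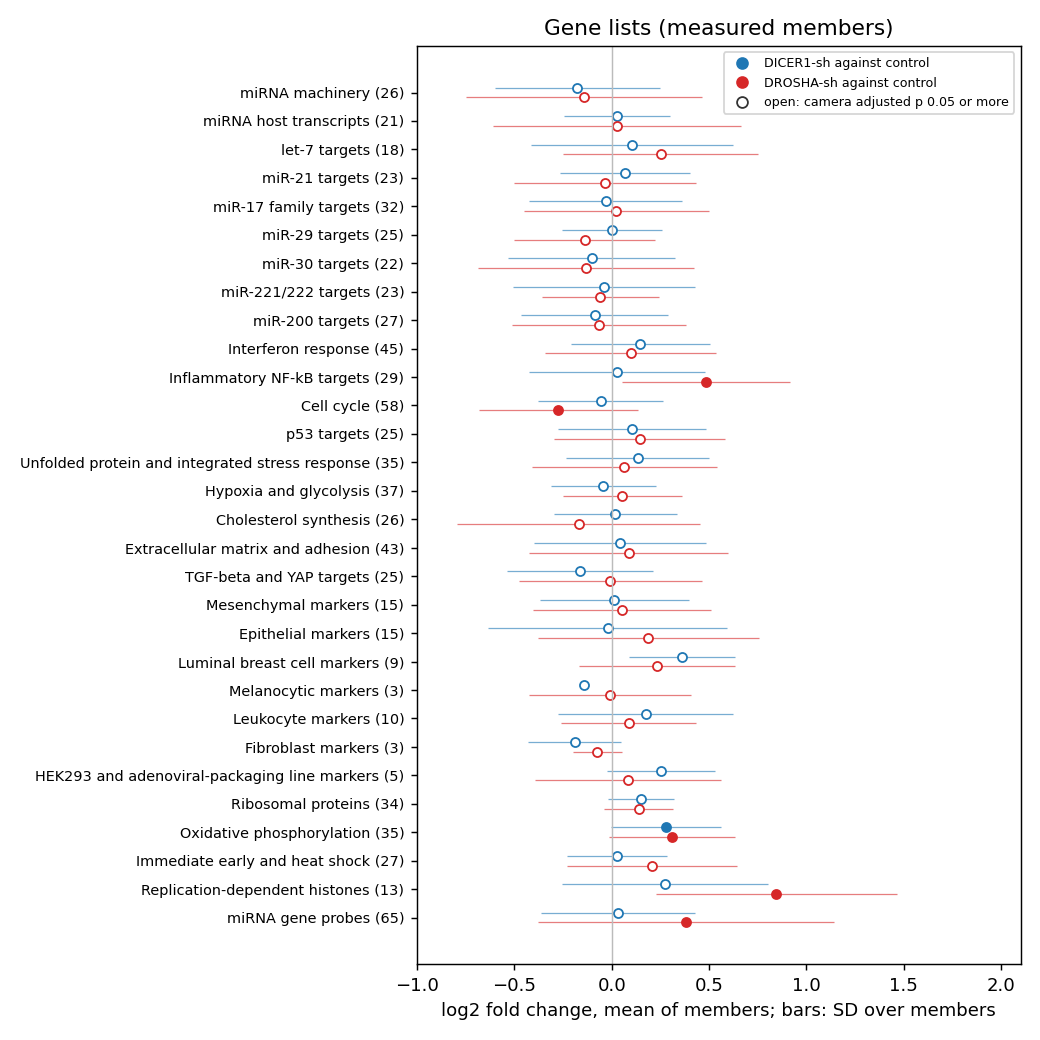
Mean log2 fold change of each gene list's measured members (horizontal axis) in DICER1-sh (blue) and DROSHA-sh (red) against control, with the SD over members as bars and the number of members in brackets. Filled points passed camera with its preset correlation, such as NF-kB targets at 0.48 and histones at 0.84 in DROSHA-sh, and no list passed with an estimated correlation.

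The direct comparison of DROSHA-sh with DICER1-sh cells tests whether the 2 knockdowns had different effects, since the control cancels. MIR21 was the 1 gene past the threshold, at least 7.12-fold higher in DROSHA-sh than in DICER1-sh (measured log2 difference 3.64, standard error 0.28, adjusted p = 0.0434 in limma). Leaving out any 1 of the 6 arrays ended this call, while the measured log2 difference stayed between 3.51 and 3.78. It was 1.95 with no background correction (adjusted p = 0.225) and 2.38 with normexp at an offset of 50 (adjusted p = 0.120), both under that bound. The count of genes past the threshold was 5 with array weights, 4 with the axis covariate and 6 with a crossed replicate block. The miRNA gene probes together were higher in DROSHA-sh by a mean log2 of 0.35 (adjusted p = 5.56e-06 in camera), with a median of 0.11. Adjusted over the list alone, 8 genes passed. That count rests on the probe filter too, since 7 of the 65 were above background on both DROSHA-sh arrays and no other. Without the probe filter the mean was 0.027 (adjusted p = 0.859), and the adjusted p was 0.171 with an estimated correlation. Among miRNA gene probes above background on all 6 arrays the mean was 0.27 (adjusted p = 0.0212). Adjusted over a list alone, MMP1 at 1.70 with a standard error of 0.29 passed on the NF-kB and extracellular matrix lists and CYP1B1 at 1.49 with a standard error of 0.29 on the miR-200 list, as did DICER1 and DROSHA among the miRNA machinery and MIR100HG among the host transcripts. Without passing stood PMEPA1, a TGF-beta target, at 1.13 with a standard error of 0.28, and KRT18, a simple epithelial keratin, at 0.96 with a standard error of 0.37.

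Of the lists, 5 differed between the knockdowns in camera. NF-kB targets were higher in DROSHA-sh by a mean log2 of 0.45 (24 of 29 above 0, adjusted p = 1.68e-08) and histones by 0.57 (12 of 13 above 0, adjusted p = 6.02e-06). With an estimated correlation neither passed (adjusted p = 0.171 and 0.417). Cell cycle genes stood at -0.22 (7 of 58 above 0, adjusted p = 5.76e-05, and 0.417 with an estimated correlation), with CKS2, a subunit of cyclin-dependent kinases, at -0.49. Cholesterol synthesis genes stood at -0.19 (adjusted p = 0.0444), with INSIG1 at -1.18 and its second probe at -0.40. Immediate early and heat shock genes stood at 0.18 (adjusted p = 0.0292), with EGR1 at 1.09. With an estimated correlation neither of these 2 lists passed (adjusted p = 0.417 for both). With 1 array left out, the immediate early list passed in 2 of 6 fits, with means of 0.098 to 0.26, and cholesterol synthesis in 4 of 6, with means of -0.29 to -0.083. Limma placed 429 of 17790 genes below an unadjusted p of 0.05 (246 higher), where chance gives 889.5. The groups did not overlap for 33.5% of genes, where chance gives 33.3%.

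The design also asks which genes respond to both knockdowns. In limma, 0 genes passed in both against control, and 71 had an unadjusted p below 0.05 in both, with 47 higher and 24 lower in both. Unchanged groups simulated against the same control arrays shared on average 102 higher and 101 lower when each gene varied on its own. With structured noise, mixed from the differences within the pairs of arrays, the median was 0 of each. The overlap therefore cannot be told from chance here. The log2 changes correlated across genes at r = 0.666, with a covariance of 0.104 and the same sign for 75.8% of genes, and genes are not independent replicates. The same simulated groups gave r = 0.501, a covariance of 0.0690 and the same sign for 66.7% of genes when each gene varied on its own. With the arrays' axis as a covariate in the fit the observed r was 0.428, below the 0.501 of those groups, which were simulated without the covariate. With structured noise, r ran from -0.973 to 0.997 over 100 draws after the extreme draws at both ends were set aside, with a covariance reaching 0.507. With control 1 given to one comparison and control 2 to the other, r was -0.031 and -0.25, but each comparison then has 1 control array and the 2 lie at opposite ends of the axis. The draws in which each gene varied on its own gave all 3 groups the same spread. The real pairs differed across genes by an SD of 0.75 in control, 0.66 in DICER1-sh and 0.30 in DROSHA-sh. A wider spread of the shared control arrays raises r, so 0.501 may be too low for unchanged groups. The shared controls may account for all of the excess in r, and no response shared by both knockdowns was shown.

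The 2 arrays of the control pair and of the DICER1-sh pair differed along 1 axis by more than the group means did, while those of the DROSHA-sh pair did not. This axis held 75.1% of the variance within groups. Control 1 (score 1.00) and DICER1-sh 2 (0.43) lay at one end and DICER1-sh 1 (-0.66) and control 2 (-0.34) at the other, with DROSHA-sh 1 (-0.22) and DROSHA-sh 2 (-0.20) side by side. Control 1 correlated with DICER1-sh 2 at r = 0.982 and with control 2 at r = 0.957 across genes. Cell cycle genes were 0.24 higher on control 1 than on control 2 on the log2 scale, and the miRNA machinery 0.41 higher. Oxidative phosphorylation genes stood at -0.80, histones at -0.69 and ribosomal proteins at -0.39 in the same difference.

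**Figure D4:**
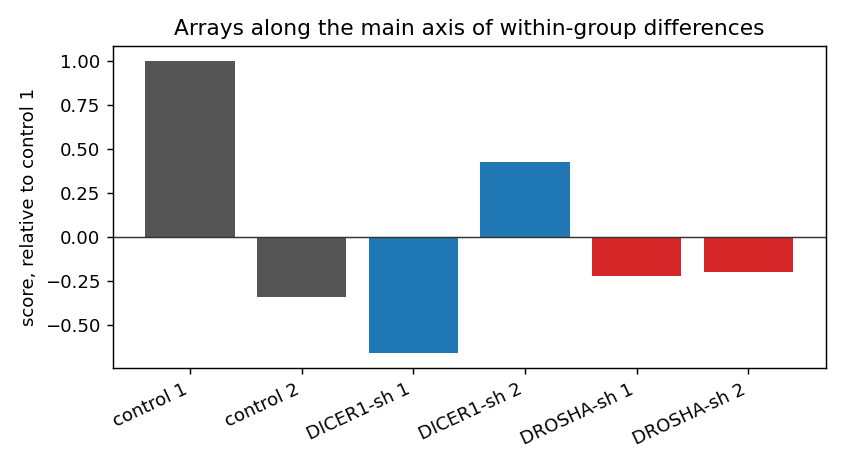
Score of each of the 6 arrays (horizontal axis) on the main axis of the differences within groups, relative to control 1 (vertical axis, no unit). Control 1 stood at 1.00 and control 2 at -0.34, and the DROSHA-sh arrays stood at -0.22 and -0.20.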

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

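All the tests of explanations in this part were chosen after the results were seen, while the differences between the knockdowns were planned comparisons.

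The miRNA gene probes that passed the filter stood out because the 2 knockdowns differed. Their mean was 0.35 higher on the log2 scale in DROSHA-sh than in DICER1-sh, with a median of 0.11. The mean was 0.027 with no filter (adjusted p = 0.859 in camera), and the call was lost with an estimated correlation (adjusted p = 0.171). MIR21 differed by a measured 3.64, at least 7.12-fold because it was not above background in DICER1-sh, but by 1.95 with no background correction and 2.38 with an offset of 50, and leaving out any 1 array ended its call with the difference at 3.51 to 3.78. The axis along which arrays of a group differed was argued against as the whole cause. With it as a covariate the mean change in DROSHA-sh was 0.35, and MIR221 and MIR185, above background on all 6 arrays, stood at 2.03 and 1.33. All 10 genes that were at least 2-fold higher by measured means stayed so, MIR181A1 only just, at 1.00. But 7 of the 10 were not above background on either control array, so their measured differences bear little on the axis. The call of the group ended when the correlation was estimated as well (adjusted p = 0.501 in camera). For dim probes, random lists of genes of like control level held at most 6 genes at least 2-fold higher in 10000 draws. Those lists were not matched on the arrays through which a probe passed the filter. Of the 65 miRNA genes, 7 were above background on both DROSHA-sh arrays and no other. The draws therefore do not settle whether dim probes and the filter explain the count of 10. The random lists were counted by measured means, as the 10 were. With bounds where control was not above background, 7 of the miRNA genes reached 2-fold. That primary transcripts may build up when DROSHA no longer cuts them stays an open hypothesis, and so does a change in their transcription: the difference of 0.348 between the knockdowns is the one that drew attention, so it decides nothing.

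Of the gene lists, NF-kB targets differed between the knockdowns by 0.45, replication-dependent histones by 0.57 and cell cycle genes by -0.22, each without a call at an estimated correlation (adjusted p = 0.171, 0.417 and 0.417). The array axis was argued against as the whole cause, because with it as a covariate the mean changes in DROSHA-sh were 0.393 for NF-kB targets, 0.698 for histones and -0.212 for the cell cycle, each past the threshold in camera with its preset correlation, though not when the correlation was estimated as well (adjusted p = 0.501, 0.686 and 0.686). Members that vary together could make the NF-kB call too easy, and this cannot be told apart from a real shift: the adjusted p was 0.273 with an estimated correlation, but that test found a simulated shift of 0.5 in 0 of 20 draws with independent noise. The estimated correlation was 0.021 between NF-kB members and -0.008 between miRNA gene probes, against the preset 0.01. It was 0.27 between histones and 0.55 between oxidative phosphorylation genes. The loss of the NF-kB and miRNA calls therefore need not come from correlated members. The knockdown of DROSHA itself stays open as a biological explanation, as do differences between stable lines that have nothing to do with miRNAs, and neither was tested.

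The split of arrays within groups was found while the replicates were compared, and no biological explanation was tested for it. A swap of control 1 with DICER1-sh 2 was argued against, because DICER1 was 1.88 higher on control 1, with a standard error of 0.57 for a difference of 2 arrays. A gene's share in the axis correlated with its span in the reference at rho = 0.369 across genes. With genes parted into 4 equal classes of span, the shortest class differed by -0.44 and the longest by 0.34 between control 1 and control 2. A difference in RNA quality or labelling that acts on long and short genes differently may contribute. The span measures neither mRNA length nor RNA quality, so it does not test this. Control 1 and DICER1-sh 2 also had at least 611 more detected probes than the other 4 arrays. That count comes from the same arrays as the axis, so it may describe the split rather than explain it. What caused the split remains open.

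Cholesterol synthesis genes differed between the knockdowns by -0.19 and immediate early and heat shock genes by 0.18, and neither passed with an estimated correlation (adjusted p = 0.417 for both). With 1 array left out these lists passed in 4 and 2 of 6 fits, and no explanation was tested.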

How the results depend on the processing

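The axis covariate, the crossed pairing, leaving out both arrays at 1 end of the axis and the filter on all 6 arrays for the miRNA gene probes were chosen after seeing the data. With 2 arrays per group the counts depend on the fit. In every alternative run, 0 genes passed in DICER1-sh against control and in both knockdowns together. In DROSHA-sh against control the count of 0 became 1 with the series matrix values, median scaling or cyclic loess, and 3 with the axis covariate. The series matrix values were raised to a floor of 16 before log2, which sets the MIR21 difference of 4.47 there. In DROSHA-sh against DICER1-sh the count of 1 became 0 with no background correction, normexp with an offset of 50, no filter, every probe on its own, only the 4 arrays of both groups and an adjusted p of 0.01, 5 with array weights and 4 with the axis covariate. Detection on all 6 arrays also gave 0, but that filter removes MIR21 before the test. With the replicate block, fitted although the numbers did not pair the samples, it was 0 and no other count or list call in the tests of genes and lists changed. A crossed replicate block gave 10 genes in DROSHA-sh against control and 6 against DICER1-sh. MIR21 against DICER1-sh passed in 6 of 19 alternatives, with a log2 difference of 1.95 to 4.47 and an adjusted p of 0.00666 to 1.00. Without control 1 and DICER1-sh 2 the counts were 0. Without control 2 and DICER1-sh 1 they were 5816 in DROSHA-sh against control and 0 against DICER1-sh, where the spread comes from the DROSHA-sh pair alone.

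Leaving out each array in turn gave 0 genes in each comparison, 0 to 4 called lists in DICER1-sh, 4 to 8 in DROSHA-sh and 3 to 5 between the knockdowns. In the same runs the change of DICER1 in its knockdown was -2.01 to -0.82, of DROSHA -2.59 to -1.92, and the mean of the miRNA gene probes was -0.020 to 0.084 in DICER1-sh, 0.33 to 0.43 in DROSHA-sh and 0.33 to 0.37 between the knockdowns. Each lone array was assumed to vary like the other groups.

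Lists called in DICER1-sh went from 1 to 4 with median scaling, 3 with no filter and 0 with the axis covariate. With that covariate 5 were called in DROSHA-sh, with let-7 targets and cholesterol synthesis in and oxidative phosphorylation out. With an estimated correlation, with fry and with both the axis and an estimated correlation, 0 lists were called in all 3 comparisons. Without control 1 and DICER1-sh 2, 0 were called in DICER1-sh and 8 in DROSHA-sh. The miRNA gene probes no longer passed in DROSHA-sh at a mean of 0.055 with no filter, where most added probes lie at background, 0.38 with an estimated correlation or fry (adjusted p = 0.273 and 0.0737) and 0.35 with the axis and an estimated correlation. Between the knockdowns these values were 0.027, 0.35 and 0.34, and 0.33 without both arrays. The sign turned for oxidative phosphorylation without control 1 (-0.12 in DICER1-sh and -0.090 in DROSHA-sh, and -0.090 in DROSHA-sh without both arrays, against 0.68 and 0.71 without control 2), miRNA gene probes in DICER1-sh without control 1 (-0.020), DICER1 in DROSHA-sh without control 2 (-0.23, against 0.95 without control 1), DROSHA in DICER1-sh without control 1 (0.20), DICER1-sh 2 (0.16) or both (0.49), against -0.47 without control 2, and MITF in DICER1-sh without DICER1-sh 2 (0.011, against -0.31 without DICER1-sh 1). The cause was not tested. Of 1606 values of named genes under 20 settings, 1584 kept their direction and side of the threshold, 13 lost the threshold, 4 gained it and 5 turned. Only MIR21 between the knockdowns was past the threshold in the main fit, so all 13 losses are its own. The 4 gains are MIR21 against control. The other values had no call to lose, so the 1584 do not measure how stable a call is. The median of all genes moved by less than 0.1 under every scaling. The seed family test and its 3 alternatives were not run because no sequences were used here. With probes above background on all 6 arrays the miRNA gene probes kept their side of the threshold in all 3 comparisons, at 0.084, 0.35 and 0.27. Genes near background have only bounds.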

Other observations

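All the tests in this part were chosen after the results were seen, and so were the genes named here.

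Of the transcripts that carry miRNA hairpins, 2 with large changes in DROSHA-sh cells are given here, while the list of host transcripts did not pass (mean 0.03, adjusted p = 0.790 in camera). MIR3142HG, the host of miR-146a, had a log2 intensity of 9.29 ± 0.37 against 6.02 ± 0.76 in control (SD, n = 2), a log2 change of 3.27 with a standard error of 0.43, and -0.23 in DICER1-sh. It was above background on 1 of the 2 control arrays. MIR100HG stood at 2.09 in DROSHA-sh and 0.13 in DICER1-sh. Neither passed limma's test over all genes (adjusted p = 0.371 for both). VMP1, the protein-coding gene that neighbours MIR21, stood at -0.10 with a standard error of 0.30. A longer VMP1 transcript that runs into the MIR21 hairpin is a candidate explanation of the MIR21 signal that stays open. The VMP1 probe was bright, with a mean log2 level of 11.82, so a small share of longer transcripts need not change its value.

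DGCR8, the RNA-binding partner of DROSHA, had a log2 intensity of 9.87 ± 0.01 in DROSHA-sh against 8.72 ± 0.20 in control and 8.74 ± 0.39 in DICER1-sh (SD, n = 2). Its transcript carries hairpins that DROSHA is known to cut, so the hypothesis was that it may build up in DROSHA-sh and not in DICER1-sh cells. The difference between the knockdowns was 1.13 with a standard error of 0.30 and did not pass limma's test over all genes (adjusted p = 1.00). The gene was picked for this difference, so the value does not test the hypothesis, which stays open.

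Among the 71 genes with an unadjusted p below 0.05 in both knockdowns were 5 members of the SPANX family of cancer-testis genes, SPANXA1, SPANXA2, SPANXB1, SPANXC and SPANXD. Their log2 changes were 1.14 to 1.25 in DICER1-sh and 1.15 to 1.60 in DROSHA-sh. The members are near-identical copies, so their probes can read each other's transcripts and do not count as 5 separate findings. ZC3H12A, an RNase that degrades inflammatory mRNAs, stood at 1.11 and 1.36, and VDR, the vitamin D receptor, at 0.99 and 0.95. With the same control arrays in both comparisons, a control value that lies low gives both knockdowns a higher value.

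With the arrays' axis as a covariate, the unnamed probe ILMN_2390310 passed beside MIR21 and MIR181B1 in DROSHA-sh against control. The covariate was drawn from the spread of these same arrays, so these calls are no independent support. Without the covariate ILMN_2390310 stood at 2.59 in DROSHA-sh and -0.11 in DICER1-sh, with 13.18 ± 0.02 against 10.59 ± 0.30 in control (SD, n = 2).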
